A study of Mus musculus with 24 samples.

How the data were processed

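RNA of mouse embryonic fibroblasts (MEFs) was sequenced after lentiviral delivery of short hairpin RNAs (shRNAs) and puromycin selection, per the labels' protocols. The 3 genotypes were a control hairpin (shControl), a hairpin against Eif2b5, which encodes eIF2B-epsilon (sheIF2B5), and that hairpin together with one against Eif4e (sheIF2B5_sheIF4E, called the combined knockdown here). From each genotype, total RNA (Total) and polysome-associated RNA (Poly) were sequenced in 4 libraries each, giving 24 libraries in 6 groups. The labels name a stranded total RNA library kit and number the libraries of each group 1 to 4, but do not say whether libraries came from separate cultures or whether a number links a Total to a Poly library.

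The deposited values are raw counts per gene, 1 column per library, with no normalization: they are whole numbers that sum to a different total in every library. The submitters' processing notes name HISAT2 2.0.4, HTSeq and the mm10 build, without stating their order, the annotation, the strand setting or the treatment of reads that map to several places. Counts of genes with near-identical copies, such as histone and ribosomal protein genes, and of overlapping or antisense genes are therefore uncertain. The table held 24061 gene symbols, of which 22548 matched a RefSeq gene of GRCm38.p6, the assembly that mm10 denotes. Positions were taken from that annotation. Library totals ran from 41785442 to 75398429 counts. No mitochondrially encoded gene was in the table, so that list could not be tested, and the alternative that left out mitochondrially encoded and ribosomal RNA genes removed only the latter.

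Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 14143, and libraries were scaled by trimmed mean of M values (TMM). A quasi-likelihood model with 1 mean per group was fitted to all 24 libraries, without a replicate block, and contrasts were tested with the quasi-likelihood F-test and Benjamini-Hochberg adjustment at 0.05. The change in polysome RNA relative to total RNA between genotypes was tested as the interaction of genotype and fraction in that model. Standard errors are the absolute log2 fold change divided by the square root of F. All p-values measure the spread between libraries of a group, which can be technical where libraries do not stem from separate cultures. Log2 fold changes are given with their standard error, and n = 4 libraries per group throughout. Values per library are TMM-scaled CPM with their SD.

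Gene lists were fixed before the data were examined. They hold 781 members in 35 lists, of which 34 could be tested and 728 members passed the filter. They cover ATF4 targets, tRNA synthetases known as ATF4 targets and other tRNA synthetases, mRNAs with regulatory upstream open reading frames (uORFs), ribosomal proteins, other mRNAs with a terminal oligopyrimidine (TOP) motif, eIF4E-sensitive mRNAs, eIF2B subunits, eIF2 with its kinases, eIF4F with the 4E-BPs, oxidative phosphorylation, mitochondrial ribosome, citrate cycle, mitochondrial stress, endoplasmic reticulum (ER) chaperones, NRF2 targets, p53 targets, S phase, G2/M phase, cholesterol synthesis, fibroblast matrix, interferon response, NF-kB targets, glycolysis, heat shock, lysosome and autophagy, replication histones, nuclear RNAs, and markers of 6 other cell types. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. A list is described as higher or lower as a set only from camera, which compares its members with the other genes.

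Named genes followed a rule fixed with the lists. Eif2b5, Eif4e and Atf4 are given in every comparison. For sheIF2B5 against shControl and for the combined knockdown against sheIF2B5, the 5 largest changes in each direction are given among genes with an adjusted p under 0.05, an average log2 CPM of at least 3, no symbol of the forms Gm, AC, AL or BC with digits, LOC, Rik or -ps and, in Total and Poly, no overlap between the libraries of both groups. From each list described, up to 4 members with the smallest p are given, both directions where both passed. Members of the lists of ATF4 targets, uORF mRNAs, eIF2B subunits and eIF4F may be named anywhere, and the combined knockdown against shControl is described for genes already named.

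Replicate numbers were checked by correlating the deviations of same-numbered libraries from their group means over 9075 genes. Within Poly all 12 pairs correlated above 0.1 (0.408 to 0.807). Within Total 10 of 12 did (-0.113 to 0.943), and Total with Poly of a genotype had a median of -0.366. Numbers thus deviated together in all Poly pairs, in most Total pairs and largely in opposite directions across fractions (number 1 of shControl, -0.77). By the rule that every pair of a fraction exceed 0.1 they pair the samples among the Poly libraries alone, although Total libraries of number 1 correlated at 0.9 to 0.943 and of number 4 at 0.744 to 0.813. Between shControl and the combined knockdown all 4 Total pairs also exceeded 0.1 (0.223 to 0.9). Values with a replicate block within each fraction are given beside a result where they change its call or move its count by over 1.5 times. Replicates were distinct libraries: 36 pairs within groups differed by 9.16 to 605 times counting noise (chi-square per degree of freedom, over genes with a summed count of at least 20) and 0 pairs were identical. The common biological coefficient of variation was 10.7%.

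Alternatives were scaling by DESeq2 size factors (RLE) or upper quartiles, leaving out ribosomal RNA genes, no filter on low counts, at least 1 CPM in 4 libraries, only the groups compared, thinning to the smallest library, DESeq2 1.42.0, limma-voom, replicate blocks over all libraries, pairing Poly with Total of a number, and by regression of Poly on Total, and leaving out each library. A block within each fraction, fits without number 1 or number 4 in all groups, and 1 more division of the shared sheIF2B5 libraries were added after the data had been seen. The sheIF2B5 libraries enter both main comparisons, so overlaps between these were set beside independent lists and divisions of those libraries, and covariances beside 20 simulations without any effect. GC content was not examined, as no genome sequence was at hand.

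The test procedure was tried on simulated counts with 200 changed genes. For sheIF2B5 against shControl it recovered 74.6%, 92.3% and 98.5% of genes changed 1.5-, 2- and 4-fold in Total, over 13409 genes tested, with 5.08% of calls false. The shares in Poly were 71.2%, 81.5% and 96.9%, with 4.24% false. For polysome relative to total, over 13420 genes tested, they were 55.0%, 82.5% and 90.6%, with 5.3% false. The simulated libraries were drawn independently, without deviations shared by a replicate number, and few of their genes changed. In the data most genes were called in Total and Poly and numbers deviated together, so these shares may not carry over.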

Results

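Transcript abundance was measured by RNA sequencing in total and in polysome-associated RNA of mouse embryonic fibroblasts, connective tissue cells grown in culture from embryos. Polysomes are mRNAs carrying several ribosomes, so the Poly libraries sample mRNA engaged in translation. Because libraries were scaled to each other by TMM, higher and lower levels are relative to the other genes of a library. A change in the total amount of polysome RNA between genotypes was not measured. Each of the 6 groups held 4 libraries. Library totals were 49241135 to 58174235 counts in shControl Total and 64415926 to 68964264 in shControl Poly. They were 48596247 to 57021296 in sheIF2B5 Total, 70930367 to 74167394 in sheIF2B5 Poly, 41785442 to 59536066 in the combined knockdown's Total and 67658381 to 75398429 in its Poly libraries. Rn45s, the ribosomal RNA precursor, took 0.96% ± 0.271 (SD, n = 4) of counts in shControl Total. Its share was 2.3% ± 0.626 in sheIF2B5 Total and 6.49% ± 5.57 in the Total libraries of the combined knockdown. Replicate 4 of the latter held 13.8%.

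Both targeted transcripts were low in every library that carried their hairpin. Eif2b5 (chromosome 16, 20498795 to 20509325), the catalytic subunit of the eIF2 exchange factor, stood at 182.9 to 189.4 CPM in the 4 shControl Total libraries, 10.25 to 11.92 CPM with sheIF2B5 and 18.91 to 22.23 CPM in the combined knockdown. These levels were 5.94% ± 0.407 and 11% ± 0.742 of the shControl mean (SD, n = 4). In Poly, Eif2b5 was at 2.72% ± 0.122 with sheIF2B5 and 8.38% ± 0.832 in the combined knockdown. Eif4e (chromosome 3, 138526191 to 138559696), the cap-binding protein, was at 7.98% ± 0.453 of shControl in Total and 3.69% ± 0.509 in Poly of the combined knockdown. With sheIF2B5 alone, where it was not targeted, Eif4e stood at 61.6% ± 4.61 in Total and 51% ± 2.87 in Poly. Atf4 (chromosome 15, 80255184 to 80257545), a transcription factor of the integrated stress response whose mRNA carries uORFs, was at 362.3 to 389.5 CPM in shControl Total and 107.7 to 113.9 CPM in shControl Poly. With sheIF2B5 it reached 678.6 to 702.4 and 555.2 to 585.2 CPM, and in the combined knockdown 214.8 to 222.5 and 102.2 to 111.7 CPM.

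**Figure D1:**
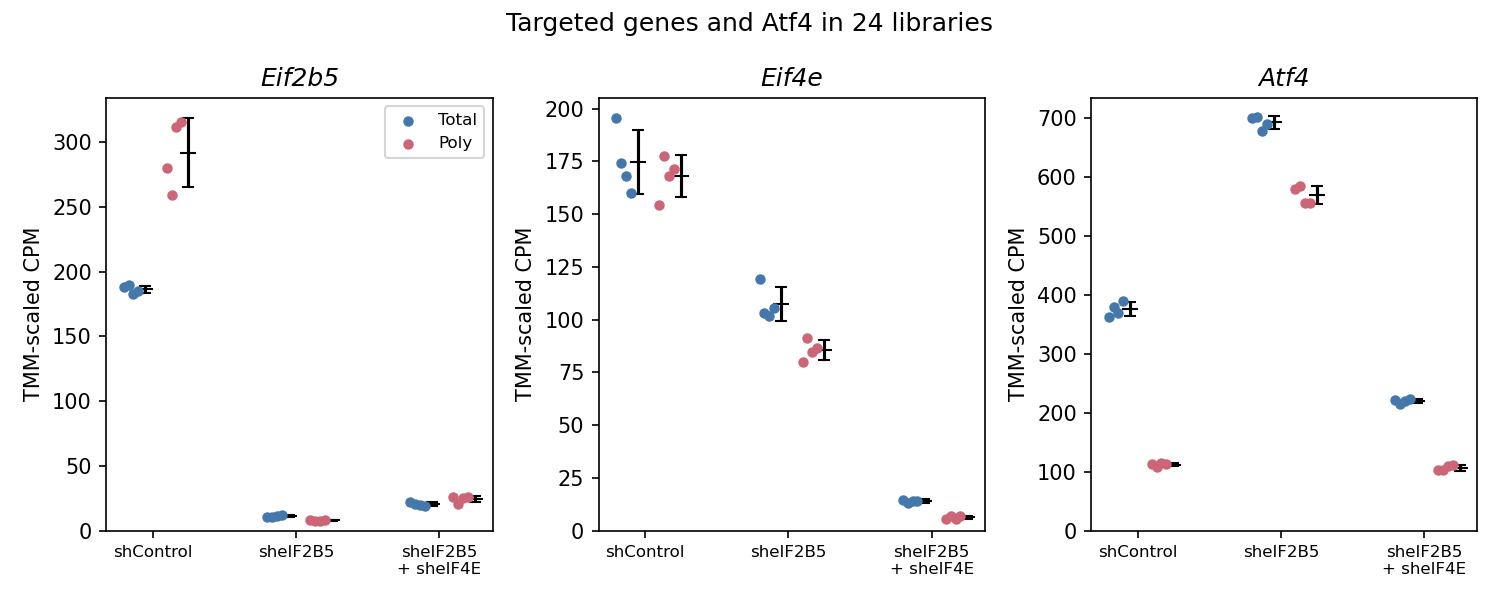
TMM-scaled CPM (linear axis from 0) of Eif2b5, Eif4e and Atf4 in the 24 libraries, by genotype and fraction; points are libraries, and the dash with its bar is the mean with the SD of 4 libraries. Eif2b5 is at 5.94% of shControl in sheIF2B5 Total and 11% in the combined knockdown, and Eif4e is at 7.98% in the latter.

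The comparison of sheIF2B5 with shControl asks how transcript levels differ when eIF2B-epsilon is depleted. In total RNA, the largest increases were in Extl1 (chromosome 4, 134356373 to 134372547), a glycosyltransferase of the exostosin family, at 6.57 ± 0.20 (log2 fold change ± SE, n = 4), and in Rsad2, the antiviral protein viperin, at 5.36 ± 0.13. They were followed by Dhrs9, a short-chain dehydrogenase (5.12 ± 0.16), Ifit3, an interferon-induced protein (4.98 ± 0.14), and Vldlr, a lipoprotein receptor (4.44 ± 0.07). Besides Eif2b5 (-4.07 ± 0.08), the largest decreases were in Hist1h2ab (-4.10 ± 0.78), Hist1h2ak (-3.46 ± 0.69) and Hist1h3f (-3.39 ± 0.56), all replication histones. Tagln (chromosome 9, 45929628 to 45936058), an actin-binding protein of contractile cells, was at -3.72 ± 0.06. Atf4 rose by 0.89 ± 0.04 and Eif4e was lower at -0.70 ± 0.08. In all, 10039 of 14143 genes changed, 5531 higher and 4508 lower, with changes above 2-fold in 1986 and 1082 of them. Of these calls 55.1% were higher, a balance that turned without number 1 in all groups. The edgeR adjusted p was 0.000108 or less for each gene named in this and the next paragraph.

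The lists of ATF4 targets, tRNA synthetases known as ATF4 targets, interferon genes, and lysosome and autophagy genes were higher with sheIF2B5. Of 41 ATF4 targets, 37 were higher, 3 lower and 1 did not pass (median 1.44, camera adjusted p = 2.51e-27). Among them were Aldh1l2, an enzyme of mitochondrial folate metabolism (3.92 ± 0.06), Gpt2, an alanine aminotransferase (2.87 ± 0.05), and Atf3 (2.83 ± 0.07). Others were Ddit3, the transcription factor CHOP (2.64 ± 0.07), Trib3 (2.92 ± 0.13), Chac1 (2.51 ± 0.11) and the asparagine synthetase Asns (1.44 ± 0.06). Of 12 tRNA synthetases known as ATF4 targets, 10 were higher and 1 lower (adjusted p = 3.86e-06, and adjusted p = 0.0504 with an estimated correlation). Cars was at 1.19 ± 0.03, Iars at 0.98 ± 0.04, Sars at 0.96 ± 0.04 and Tars at 0.70 ± 0.03. Of 25 genes of the interferon response, 24 were higher and 0 lower (median 2.73, adjusted p = 7.46e-20), including Oasl2 (4.42 ± 0.12), Gbp3 (3.43 ± 0.09) and Ifit1 (3.01 ± 0.08). Among 25 lysosome and autophagy genes, 20 were higher and 3 lower (adjusted p = 9.88e-09). Gpnmb was at 3.85 ± 0.16, the autophagosome marker Map1lc3b at 1.88 ± 0.05, the proton pump subunit Atp6v0d1 at 1.35 ± 0.04 and the protease Ctsb at 1.33 ± 0.06. The proliferation lists fell. All 26 S phase genes were lower (median -1.19, adjusted p = 3.76e-20), such as Mcm5 (-1.76 ± 0.06), Rrm2 (-1.73 ± 0.05), Tyms (-1.44 ± 0.05) and Mcm7 (-1.42 ± 0.05). So were all 25 G2/M genes (median -1.48, adjusted p = 2.03e-32), such as Cenpa (-2.58 ± 0.06), Ccna2 (-2.42 ± 0.06), Ube2c (-2.22 ± 0.07) and Ccnb2 (-1.61 ± 0.04). Of 18 replication histones 17 were lower, among them Hist1h1b (-2.95 ± 0.21) and Hist1h1a (-2.68 ± 0.10) (adjusted p = 0.0138, and adjusted p = 0.8 with an estimated correlation). Of the 5 eIF2B subunits 3 were lower, Eif2b5 with Eif2b4 (-0.83 ± 0.06) and Eif2b1 (-0.75 ± 0.05) (adjusted p = 3.59e-04). This list holds Eif2b5, the hairpin's own target, whose decrease adds to the downward test. The list was not tested without Eif2b5, here or in any other comparison, so how far the call rests on Eif2b5 is not known.

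Metabolic and structural lists were mixed in total RNA. Among 29 genes of the fibroblast matrix, 9 were higher and 12 lower (adjusted p = 0.0195, up to 0.274 over the alternatives, and adjusted p = 0.441 with an estimated correlation). The lower ones included Tagln, the smooth muscle actin Acta2 (-2.78 ± 0.07), the growth factor receptor Pdgfra (-1.41 ± 0.05) and Ctgf (-1.38 ± 0.05). Of 18 glycolysis genes, 10 were lower and 3 higher (adjusted p = 0.0301, and adjusted p = 0.543 with an estimated correlation). Aldoa (-1.32 ± 0.08), Ldha (-1.27 ± 0.05) and Pgam1 (-1.11 ± 0.07) were lower and Hk2 (0.76 ± 0.05) was higher. Heat shock genes were lower in 12 and higher in 2 of 15, with Chordc1 at -0.93 ± 0.08 and Dnajb1 at -0.64 ± 0.04 (adjusted p = 0.0322, and adjusted p = 0.0618 with an estimated correlation). Of 76 mitochondrial ribosome genes 38 were lower and 11 higher (adjusted p = 0.0237, and adjusted p = 0.495 with an estimated correlation), among them Mrps27 at -1.88 ± 0.07 and Mrpl10 at -1.03 ± 0.05. In every list named so far for this comparison, the counts adjusted over the list alone were the same, and 6 of the 12 calls held with an estimated correlation.

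Other lists had no camera call in total RNA with sheIF2B5. Ribosomal proteins were higher in 7 and lower in 30 of 78 (adjusted over the list alone 6 and 28; adjusted p = 0.089), which became a call without replicate 1 of shControl Total (0.0469), with no filter (0.00619), with only the groups compared (0.0161) and with limma-voom (0.0224). Of 13 uORF mRNAs 8 were higher and 3 lower (adjusted p = 0.0649, or 0.0367 with a replicate block within each fraction). Without replicate 1 of sheIF2B5 Total or of sheIF2B5 Poly that list had adjusted p = 0.049 and 0.0445. Higher and lower genes numbered 7 and 10 of 24 other TOP mRNAs (adjusted p = 0.626), 2 and 3 of 8 other tRNA synthetases (0.89), 4 and 4 of 11 genes of eIF2 and its kinases (0.71) and 6 and 7 of 15 genes of eIF4F and the 4E-BPs (0.185). They numbered 8 and 8 of 22 eIF4E-sensitive mRNAs (0.826), 7 and 8 of 20 mitochondrial stress genes (0.667), 6 and 10 of 18 NRF2 targets (0.138), 10 and 9 of 23 cholesterol synthesis genes (0.835), 9 and 2 of 14 NF-kB targets (0.749) and 4 and 2 of 10 nuclear RNAs (0.889). Of 20 p53 targets 7 were higher and 9 lower (0.758, and 7 and 10 adjusted over the list alone), with a median of -0.16 but a mean of 0.39 and an upward test. Trp53 itself had 0 counts in all 24 libraries. Counts were 20 and 19 of 74 oxidative phosphorylation genes (0.63; 19 and 19 adjusted over the list alone), 9 and 4 of 19 citrate cycle genes (0.889) and 9 and 7 of 23 ER chaperones (0.358). The balance of these 3 lists turned with DESeq2 size factors. The signs of median, mean and test differed for other tRNA synthetases, eIF4E-sensitive mRNAs, eIF2 and its kinases, oxidative phosphorylation, ER chaperones, nuclear RNAs and macrophage markers. The few measurable markers of other cell types gave no call: adjusted p = 0.71 for 4 endothelial genes (2 higher, 0 lower) and for 4 macrophage genes (1 and 3), and 0.758 for 2 epithelial genes (2 and 0). It was 0.806 for 3 muscle genes (2 and 0), 0.901 for 3 adipocyte genes (2 and 1) and 0.441 for 5 neural genes (3 and 1). Adjusted over the list alone, counts without a second value were the same. Counts of histone genes rest on near-identical copies whose reads the counting could have split.

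Polysome RNA moved with total RNA for most genes: 4700 were higher and 4130 lower in both, and the log2 fold changes correlated at r = 0.92 across genes, which are not independent replicates. In Poly, 10112 genes changed with sheIF2B5, 5084 higher and 5028 lower. Extl1 (6.24 ± 0.19), Rsad2 (5.56 ± 0.12), Dhrs9 (4.94 ± 0.15), Oasl2 (4.65 ± 0.12) and Vldlr (4.63 ± 0.07) rose furthest. Eif2b5 (-5.20 ± 0.08), Tagln (-4.08 ± 0.06), the X-inactivation RNA Xist (-3.72 ± 0.10), Hist1h2bl (-3.67 ± 0.61) and Arhgdia, an inhibitor of Rho GTPases (-3.60 ± 0.12), fell furthest. Atf4 was up by 2.35 ± 0.04 in Poly, and Eif4e was at -0.97 ± 0.08. Of 13 uORF mRNAs 9 were higher and 3 lower (adjusted p = 9.7e-04), with Atf5 at 2.60 ± 0.14, Ddit3 at 2.30 ± 0.07 and Ppp1r15b at -1.40 ± 0.04. Of 78 ribosomal protein genes, 69 were lower and 1 higher (median -0.90, adjusted p = 2.03e-11). Rpl7a was at -1.41 ± 0.06, Rpl6 and Rps7 at -1.31 ± 0.05 and -1.31 ± 0.04, and Rpl15 at -1.09 ± 0.05. Other TOP mRNAs were lower in 21 of 24 and higher in 0 (adjusted p = 3.86e-04, and adjusted p = 0.207 with an estimated correlation). They included Gnb2l1 (-0.90 ± 0.05), Naca (-0.86 ± 0.05), Cct4 (-0.76 ± 0.05) and Eef1b2 (-0.63 ± 0.04).

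The 12 lists called in total RNA were also called in Poly with sheIF2B5. ATF4 targets were higher in 36 and lower in 2 of 41, with Aldh1l2 at 3.90 ± 0.06 (median 1.37). The same held for ATF4-type tRNA synthetases in 10 and 1 of 12, interferon genes in 24 and 0 of 25, and lysosome genes in 21 and 3 of 25. S phase and G2/M genes were lower in all 26 and all 25, histones in 16 of 18, and eIF2B subunits in 3 of 5. Heat shock genes were lower in 12 and higher in 1 of 15, among them Hsph1 (-1.27 ± 0.09) and Dnajb1 (-0.74 ± 0.04). Adjusted over the list alone, 2 tRNA synthetases were lower and all other counts given here for Poly were the same. The histone call had adjusted p = 0.0181, and adjusted p = 0.666 with an estimated correlation. Matrix genes were higher in 8 and lower in 14 (0.0111, up to 0.278 over the alternatives, and adjusted p = 0.417 with an estimated correlation), and glycolysis genes in 3 and 12 (0.0314, 0.0538 with at least 1 CPM in 4 libraries, and adjusted p = 0.526 with an estimated correlation). Mitochondrial ribosome genes were higher in 11 and lower in 41 (0.0247, and adjusted p = 0.474 with an estimated correlation).

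Relative to total RNA, TOP mRNAs were lower in Poly with sheIF2B5, and some uORF mRNAs, with Atf4 first, were higher. Atf4 rose by 1.46 ± 0.05 in Poly beyond its change in Total (edgeR adjusted p = 6.8e-15). It was followed by Sephs2, an enzyme of selenocysteine synthesis (0.96 ± 0.08), the cell cycle factor E2f1 (0.96 ± 0.09), Atf5 (0.89 ± 0.18) and Hilpda, a lipid droplet protein (0.75 ± 0.09). The largest decreases were in Rpl23a (-1.26 ± 0.19), Rps7 (chromosome 12, 28630847 to 28635953; -1.17 ± 0.05), Rplp0 (-1.15 ± 0.20), Prkrir (-1.14 ± 0.09) and Rps19 (-1.13 ± 0.11). Eif2b5 was lower at -1.13 ± 0.10, and Eif4e, at -0.27 ± 0.11, did not pass (adjusted p = 0.167, or 0.000915 with a replicate block within each fraction). Of 78 ribosomal protein genes 59 were lower and 0 higher, or 64 and 0 adjusted over the list alone (median -0.72 beside -0.06 for all genes, adjusted p = 2.87e-101). Rpl6 was at -0.84 ± 0.07 and Rpl10 at -0.81 ± 0.08. Of 24 other TOP mRNAs 18 were lower and 0 higher, or 20 and 0 adjusted over the list alone (adjusted p = 2.6e-35). They included Eef1b2 (-1.04 ± 0.06), Gnb2l1 (-0.90 ± 0.08), Eif3f (-0.71 ± 0.07) and Eif3h (-0.55 ± 0.06). Among 13 uORF mRNAs, Atf4, Atf5 and Ibtk (0.58 ± 0.09) were higher and Ddit3 (-0.34 ± 0.09) was lower, or 4 and 2 adjusted over the list alone (adjusted p = 9.1e-12). The call of Ddit3 (adjusted p = 0.0305) ended when any 1 of 11 libraries was left out (0.0512 to 0.0746). Of 10 nuclear RNAs 4 were lower and 0 higher, or 7 and 1 adjusted over the list alone (adjusted p = 1.5e-05). These 4 were Meg3 (-1.41 ± 0.33; adjusted p = 0.0117, or 0.078 with limma-voom), Malat1 (-0.89 ± 0.10), Xist (-0.84 ± 0.13) and Neat1 (-0.66 ± 0.13). Among the 5 eIF2B subunits the call (adjusted p = 0.0143) came with 1 lower gene, Eif2b5, and ended without replicate 1 of shControl Total (0.0538), with no filter (0.0855) and with limma-voom (0.235). All 5 lists called here held with an estimated correlation. With the block by regression of Poly on Total, Hilpda (adjusted p = 0.0633), Eif3h (0.352), Xist (0.0711) and Meg3 (0.378) lost their calls. Sephs2 (-0.40, 0.627), E2f1 (-0.019, 0.961) and Malat1 (0.25, 0.495) lost theirs and turned, and Ddit3 passed the other way (3.62, 0.0119). The regression subtracts a slope fitted within groups (median -0.26) times the Total change, not the whole Total change. A negative slope adds a multiple of the Total change, so these values are a different quantity from the interaction. With the block pairing Poly with Total of a number, Atf5 (0.0611) and Ddit3 (0.166) lost theirs. ATF4-type tRNA synthetases were not called (adjusted p = 0.351), but were as higher with DESeq2 size factors (0.0283), no filter (0.0144), at least 1 CPM in 4 libraries (0.0169), DESeq2 (0.0165) and without number 1 in all groups (2.69e-04). Without number 1, genes of oxidative phosphorylation (0.00188), ER chaperones and lysosome genes (0.00473 each) and the citrate cycle (0.041) were also called as higher, histones as lower (0.0362), and the eIF2B call ended (0.133). Genes listed as sensitive to eIF4E were lower in 1 and higher in 0 of 22 (adjusted p = 0.666).

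In all, 750 genes changed in polysome relative to total RNA, 168 higher and 582 lower, and 3040 did with a replicate block within each fraction. The share of higher genes was 22.4% of calls but 57.5% with DESeq2 size factors, and the count fell to 416 without replicate 1 of sheIF2B5 Poly. The number of ribosomal protein genes that were lower stayed between 51 and 58 under the other scalings and filters.

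The combined knockdown was compared with sheIF2B5 to ask what depletion of eIF4E adds when eIF2B-epsilon is already low. In total RNA the largest increases were in Scn5a (chromosome 9, 119483404 to 119579030), a voltage-gated sodium channel (3.71 ± 0.14), and Lars2, the mitochondrial leucyl-tRNA synthetase (3.23 ± 0.62). They were followed by Nrep (3.11 ± 0.10), Plau, the urokinase-type plasminogen activator (2.77 ± 0.06), and the orphan receptor Gpr153 (2.73 ± 0.13). The largest decreases were in Extl1 (-4.73 ± 0.17), Tnfrsf11b (chromosome 15, 54250619 to 54278484), the decoy receptor osteoprotegerin (-4.04 ± 0.07). Next were Zcchc5 (-3.92 ± 0.10), the BMP antagonist Chrdl1 (-3.54 ± 0.08) and Smad9 (-3.29 ± 0.09). Atf4 fell by 1.66 ± 0.04 and Eif4e by 2.95 ± 0.08, while Eif2b5 was 0.89 ± 0.07 higher than with sheIF2B5 alone. In all, 9669 genes changed, 4040 higher and 5629 lower, and with all libraries the edgeR adjusted p was 7.55e-05 or less for each gene given with a fold change here and in the next paragraph. The counts of Lars2 ran from 22821 in a shControl Poly library with 0.273% Rn45s to 1667072 in replicate 4 of the combined knockdown's Total, with 13.8%. In 1 pair of libraries with similar shares the counts differed. They were 124732 in replicate 3 of sheIF2B5 Total (3.08% Rn45s) and 429854 in replicate 2 of the combined knockdown's Total (2.9%). Within the combined knockdown's Total, counts rose with the Rn45s share, and the cause was not tested. They were 240318 in replicate 1 (1.46%), 1008335 in replicate 3 (7.84%) and 1667072 in replicate 4. Counts also rose with the share in sheIF2B5 Poly, from 40315 (0.433%) to 147348 (2.44%). In the combined knockdown's Poly they rose from 191361 (1.43%) to 681863 (4.91%). In sheIF2B5 Total and both shControl groups the order of counts did not follow the share throughout. The mean Rn45s share was 6.49% in the combined knockdown's Total libraries and 2.3% in those of sheIF2B5. Without replicate 4 of the combined knockdown's Total the log2 fold change of Lars2 was 2.37 and its adjusted p stayed under 0.05.

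The lists of ATF4 targets, ATF4-type tRNA synthetases, lysosome and autophagy genes, cholesterol synthesis and NRF2 targets were lower when the Eif4e hairpin was added. Of 41 ATF4 targets 37 were lower and 0 higher, or 39 and 0 adjusted over the list alone (median -1.36, adjusted p = 7.05e-34). They included Aldh1l2 (-2.88 ± 0.06), Gpt2 (-2.57 ± 0.05), Atf3 (-2.51 ± 0.07), the serine synthesis enzyme Psph (-2.26 ± 0.05), Atf5 (-1.83 ± 0.13) and Ddit3 (-1.62 ± 0.06). All 12 ATF4-type tRNA synthetases were lower (adjusted p = 7.46e-08), such as Cars (-0.98 ± 0.03), Yars (-0.96 ± 0.05), Sars (-0.94 ± 0.04) and Iars (-0.87 ± 0.04). Lysosome and autophagy genes were lower in 21 and higher in 2 of 25 (adjusted p = 4.49e-11). Map1lc3b was at -2.28 ± 0.05, the autophagy receptor Nbr1 at -1.44 ± 0.05, Hexa at -1.35 ± 0.06 and Atp6v0d1 at -0.90 ± 0.04. Of 23 cholesterol synthesis genes 19 were lower and 2 higher, or 20 and 2 adjusted over the list alone (median -0.80, adjusted p = 7.67e-11). They included Insig1, which retains the sterol sensor in the ER (-2.04 ± 0.04), Lss (-1.53 ± 0.05), Sqle (-1.41 ± 0.04) and Fdft1 (-1.36 ± 0.05), the latter 3 enzymes of the pathway. NRF2 targets were lower in 12 and higher in 3 of 18 (adjusted p = 6.62e-05). The cystine transporter Slc7a11 was at -2.77 ± 0.08, Gsta4 at -2.21 ± 0.09, Gstm1 at -1.52 ± 0.05 and the thioredoxin reductase Txnrd1 at -1.16 ± 0.03. The proliferation lists rose. Of 26 S phase genes 23 were higher and 0 lower (median 0.69, adjusted p = 1.85e-12), with Ccne2 at 1.77 ± 0.10, Ccne1 at 1.55 ± 0.05, Rrm2 at 1.38 ± 0.05 and Mcm7 at 1.27 ± 0.05. Of 25 G2/M genes 23 were higher and 0 lower (adjusted p = 4.49e-11), with Ccna2 at 1.51 ± 0.05, Bub1 at 1.33 ± 0.08, Ndc80 at 1.26 ± 0.07 and Birc5 at 0.87 ± 0.05. NF-kB targets were higher in 8 and lower in 1 of 14 (adjusted p = 7.28e-05). The prostaglandin synthase Ptgs2 was at 1.45 ± 0.06, the chemokine Ccl2 at 1.44 ± 0.06, Vcam1 at 1.27 ± 0.06 and Tnfaip3 at 0.81 ± 0.06. These 8 lists also held with an estimated correlation.

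A further 8 lists were called in total RNA and were lost with an estimated correlation. Matrix genes were higher in 14 and lower in 9 of 29 (adjusted p = 3.8e-04, and adjusted p = 0.167 with an estimated correlation). Acta2 was at 2.58 ± 0.07, Ctgf at 2.13 ± 0.05, Tagln at 2.03 ± 0.06 and the collagen cross-linking enzyme Lox at -1.29 ± 0.05. Interferon genes were higher in 12 and lower in 6 of 25 (0.0233, 0.087 with a replicate block within each fraction, and adjusted p = 0.341 with an estimated correlation). Cxcl10 was at 2.33 ± 0.09, Rsad2 at 1.71 ± 0.08, Oasl1 at 1.60 ± 0.10 and Gbp2 at -0.94 ± 0.07. Glycolysis genes were higher in 10 and lower in 3 of 18, or 11 and 3 adjusted over the list alone (0.00193, and adjusted p = 0.309 with an estimated correlation). The lactate exporter Slc16a3 was at 2.06 ± 0.15, Pdk1 at 2.0 ± 0.07, Aldoa at 1.58 ± 0.08 and Ldha at 1.10 ± 0.05. Genes of oxidative phosphorylation were lower in 54 and higher in 3 of 74 (0.0042, and adjusted p = 0.411 with an estimated correlation), such as Ndufb4 (-1.65 ± 0.08), Ndufa1 (-1.44 ± 0.09), Sdhc (-1.33 ± 0.06) and Ndufc1 (-1.11 ± 0.08). Citrate cycle genes were lower in 10 and higher in 2 of 19 (0.0317, and adjusted p = 0.441 with an estimated correlation). Ogdh was at -1.94 ± 0.05, Idh3a at -1.57 ± 0.06, Suclg2 at -1.03 ± 0.06 and Pdhb at -0.84 ± 0.06. ER chaperone genes were lower in 17 and higher in 3 of 23 (0.0233, and adjusted p = 0.411 with an estimated correlation). Herpud1 was at -1.68 ± 0.04, Xbp1 at -0.95 ± 0.04, Sel1l at -0.78 ± 0.04 and Edem1 at -0.69 ± 0.05. Ribosomal protein genes were lower in 57 and higher in 0 of 78, or 59 and 0 adjusted over the list alone (0.00863, and adjusted p = 0.411 with an estimated correlation). Rps11 was at -1.03 ± 0.08 and Rpl10 at -0.74 ± 0.05. Of 13 uORF mRNAs 6 were lower and 2 higher (0.0369, 0.0563 with a replicate block within each fraction, and adjusted p = 0.0813 with an estimated correlation). The eIF2B subunits, higher in 4 and lower in 0 of 5, gave no call (adjusted p = 0.0537, or 0.038 with that block), which became one when any 1 of 5 libraries was left out (0.045 to 0.0498). Over the alternatives, adjusted p reached 0.179 for the citrate cycle, 0.0733 for ER chaperones, 0.087 for interferon genes and 0.312 for uORF mRNAs. Of 18 histones 5 were higher and 1 lower, also without a call (0.191, or 0.0478 with that block). Where no second count stands beside a list in this or the preceding paragraph, that adjusted over the list alone was the same.

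**Figure D2:**
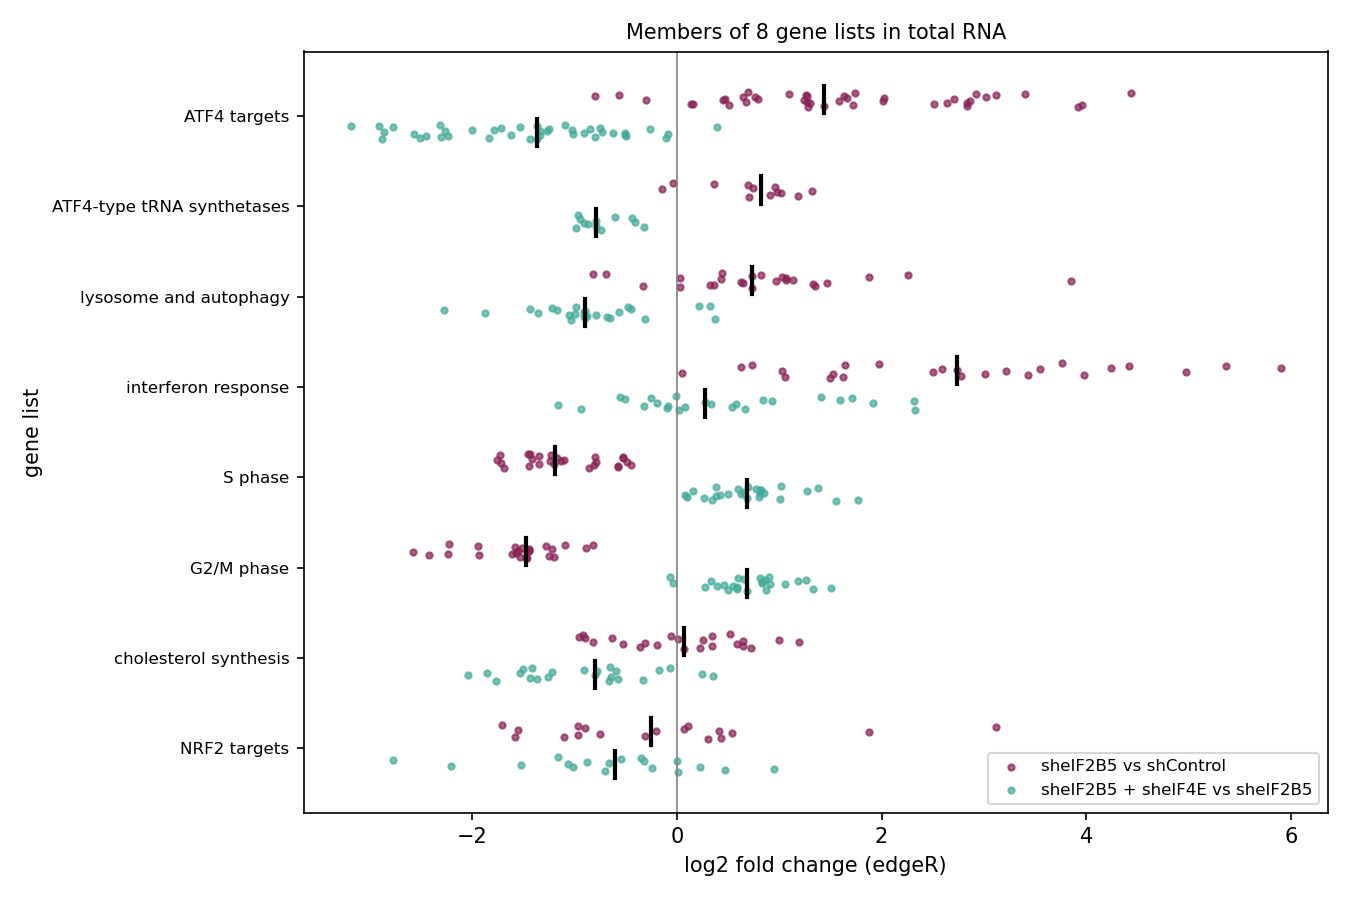
Log2 fold change in total RNA (edgeR, horizontal axis) of the members of 8 gene lists, with points for genes and black bars for medians, for sheIF2B5 against shControl and for the combined knockdown against sheIF2B5. The median of the 41 ATF4 targets lies at 1.44 in the first comparison and at -1.36 in the second, and that of the 26 S phase genes at -1.19 and 0.69.

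In Poly, 9862 genes differed between the combined knockdown and sheIF2B5, 4966 higher and 4896 lower. Scn5a (3.91 ± 0.14), Nrep (3.52 ± 0.10), Plau (3.16 ± 0.07), Gpr153 (3.13 ± 0.13) and the sphingomyelinase Smpd3 (2.87 ± 0.08) rose furthest. Extl1 (-4.65 ± 0.16), Tnfrsf11b (-4.13 ± 0.07), Eif4e (-3.79 ± 0.09), Zcchc5 (-3.54 ± 0.09) and Chrdl1 (-3.52 ± 0.08) fell furthest. Atf4 fell by 2.42 ± 0.04 and Eif2b5 was 1.62 ± 0.07 higher. Of 41 ATF4 targets 38 were lower and 1 higher (adjusted p = 1.74e-28), such as Gpt2 (-2.79 ± 0.05), Aldh1l2 (-2.71 ± 0.06), Atf3 (-2.62 ± 0.07) and Psph (-2.33 ± 0.05). Cholesterol synthesis genes were lower in 20 and higher in 2 of 23 (adjusted p = 1.38e-10), with Insig1 at -2.43 ± 0.05, and lysosome genes in 22 and 2 of 25 (adjusted p = 3.48e-11), with Map1lc3b at -2.50 ± 0.05. S phase and G2/M genes were each higher in 23 and lower in 0 (of 26 and 25; adjusted over the list alone 25 and 0, and 24 and 1; adjusted p = 2.94e-13 and 1.38e-10). NF-kB targets were higher in 9 of 14 (adjusted p = 2.94e-04) and NRF2 targets lower in 12 and higher in 4 of 18 (adjusted p = 1.57e-04). Matrix genes were higher in 18 and lower in 3 of 29, or 19 and 3 adjusted over the list alone (adjusted p = 9.05e-07, and adjusted p = 0.0516 with an estimated correlation). Tagln was at 2.11 ± 0.06, Acta2 at 2.10 ± 0.07, Ctgf at 2.08 ± 0.05 and the microfibril protein Fbn1 at 1.90 ± 0.05. Of 13 uORF mRNAs, 5 were lower, including Atf5 (-2.41 ± 0.13) and Ddit3 (-1.50 ± 0.07), and 4 higher. The camera call was down at adjusted p = 0.0297 with a mean of -0.50 but a median of 0.05, and was lost with an estimated correlation (adjusted p = 0.0697 with an estimated correlation) and with a replicate block within each fraction (0.0888), and adjusted p reached 0.537 over the alternatives.

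Further lists were called in Poly and lost with an estimated correlation. ATF4-type tRNA synthetases were lower in 11 and higher in 0 of 12 (adjusted p = 0.00114, and adjusted p = 0.165 with an estimated correlation). Oxidative phosphorylation genes were lower in 53 and higher in 6 of 74 (0.00114, and adjusted p = 0.349 with an estimated correlation). Mitochondrial ribosome genes were lower in 49 and higher in 7 of 76 (0.0447, 0.0539 without replicate 4 of sheIF2B5 Poly, and adjusted p = 0.512 with an estimated correlation), and ER chaperones lower in 15 and higher in 5 of 23 (0.0474, and adjusted p = 0.512 with an estimated correlation). The ER call ended when any 1 of 5 libraries was left out (0.051 to 0.0626). Over the alternatives, adjusted p reached 0.0918 for the former and 0.0904 for the latter. Interferon genes were higher in 15 and lower in 4 of 25 (0.00622, and adjusted p = 0.215 with an estimated correlation), and glycolysis genes higher in 10 and lower in 0 of 18 (0.00114, and adjusted p = 0.258 with an estimated correlation). Adjusted over the list alone, 8 mitochondrial ribosome genes and 6 ER chaperones were higher, and other counts without a second value were the same. Citrate cycle genes were not called (adjusted p = 0.0551), but were called when any 1 of 7 libraries was left out (0.0371 to 0.0497), and eIF2B subunits (0.0776) were called without replicate 2 of the combined knockdown's Poly (0.0447). Ribosomal protein genes were higher in 11 and lower in 10 of 78 in Poly, a balance that turned to 8 and 13 with DESeq2 size factors (adjusted over the list alone 7 and 7; adjusted p = 0.992).

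Relative to total RNA, the Poly level of Atf4 fell by 0.76 ± 0.05 when the Eif4e hairpin was added (edgeR adjusted p = 1.65e-09), and Eif4e itself by 0.84 ± 0.11, while Eif2b5 was 0.74 ± 0.10 higher. The largest increases were in Zbed4 (1.90 ± 0.44), Dync1h1 (chromosome 12, 110601395 to 110666944), the heavy chain of cytoplasmic dynein (1.51 ± 0.07), the basement membrane proteoglycan Hspg2 (1.10 ± 0.37), the DNA repair kinase Prkdc (1.06 ± 0.10) and Dync2h1 (0.93 ± 0.10). The call of Hspg2 (adjusted p = 0.0325) ended when any 1 of 9 libraries was left out (0.0508 to 0.0763). The largest decreases were in Sfr1 (-1.12 ± 0.07), Gdpd1 (-1.09 ± 0.10), C78339 (-1.08 ± 0.10), Abhd16a (-1.07 ± 0.26) and Uchl5 (-1.06 ± 0.11). Of 78 ribosomal protein genes 42 were higher and 0 lower, or 51 and 0 adjusted over the list alone (adjusted p = 5.17e-11, and adjusted p = 0.109 with an estimated correlation). Their median was 0.43 beside 0.13 for all genes, with Rps27a at 0.88 ± 0.13, Rpl10 at 0.67 ± 0.08, Rpl14 at 0.66 ± 0.09 and Rpl6 at 0.62 ± 0.07. The rise went with lower Total levels rather than higher Poly levels. Against shControl, the median of ribosomal protein genes in Total was -0.15 with sheIF2B5 and -0.61 in the combined knockdown. In Poly it was -0.90 in both. Other TOP mRNAs were higher in 11 and lower in 1 of 24, or 14 and 1 adjusted over the list alone (5.89e-06, and adjusted p = 0.163 with an estimated correlation). Eef1b2 was at 0.70 ± 0.06, Eif4b at 0.68 ± 0.06, Eif3f at 0.60 ± 0.07 and Gnb2l1 at 0.57 ± 0.08. Of 12 ATF4-type tRNA synthetases 10 were higher and 0 lower, or 11 and 0 adjusted over the list alone (7.86e-05, and adjusted p = 0.163 with an estimated correlation). Aars was at 0.38 ± 0.06. Iars, at 0.33 ± 0.06, and Cars and Tars, at 0.26 ± 0.05 each, no longer passed without ribosomal RNA genes (adjusted p = 0.0545, 0.0678 and 0.114). Matrix genes were higher in 16 and lower in 2 of 29, or 17 and 2 adjusted over the list alone (6.33e-05, and adjusted p = 0.163 with an estimated correlation). Fn1 was at 0.84 ± 0.07, Fbn1 at 0.65 ± 0.07, Tnc at 0.57 ± 0.07 and Thbs1 at 0.51 ± 0.07. Mitochondrial ribosome genes were lower in 15 and higher in 6 of 76, or 16 and 6 adjusted over the list alone (3.38e-05, and adjusted p = 0.163 with an estimated correlation). Mrps30 (-0.74 ± 0.08), Mrpl47 (-0.73 ± 0.12) and Mrps2 (-0.58 ± 0.06) were lower and Mrpl44 (0.35 ± 0.05) was higher. Genes listed as sensitive to eIF4E were lower in 6 and higher in 1 of 22, or 7 and 2 adjusted over the list alone (adjusted p = 0.107), with a median of 0.07 but a downward test. Their direction was called with DESeq2 size factors (0.0409) or DESeq2 (0.0417), without ribosomal RNA genes (0.034) and without number 1 in all groups (0.0332). With the block by regression of Poly on Total, Atf4 (-1.597, adjusted p = 0.198), Eef1b2 (0.459), Eif4b (0.712), Gnb2l1 (0.162), Rpl6 (0.891), Rpl14 (0.749), Rps27a (0.301), Dync2h1 (0.558), Sfr1 (0.176), Cars (0.866) and Mrps2 (0.592) lost their calls. Eif3f (0.504), Gdpd1 (0.34), Uchl5 (0.606), Aars (0.0543), Tars (0.71), Fn1 (0.684), Thbs1 (0.936), Mrps30 (0.768) and Mrpl44 (0.681) lost theirs and turned. Rpl10 (-0.79, 0.0166) and Iars (-0.84, 0.00346) passed the other way. With the block pairing Poly with Total, Hspg2 lost its call (0.168). Lysosome genes, not called (0.293), were called as lower with DESeq2 size factors (0.0409), without ribosomal RNA genes (0.0377) and with DESeq2 (0.0302), and oxidative phosphorylation genes (0.214) without number 1 (0.0332). S phase genes were higher in 13 and lower in 2 of 26, or 14 and 3 adjusted over the list alone, which turned to 4 and 5 with DESeq2 size factors (adjusted p = 0.119, or 0.0158 with a replicate block within each fraction).

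In all, 3288 genes changed in polysome relative to total RNA between the knockdowns, 2488 higher and 800 lower, and 5974 did with a replicate block within each fraction. The share of higher genes was 75.7% of calls but 36.1% of 2136 calls with DESeq2 size factors and 32.2% of 2184 calls without ribosomal RNA genes.

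**Figure D3:**
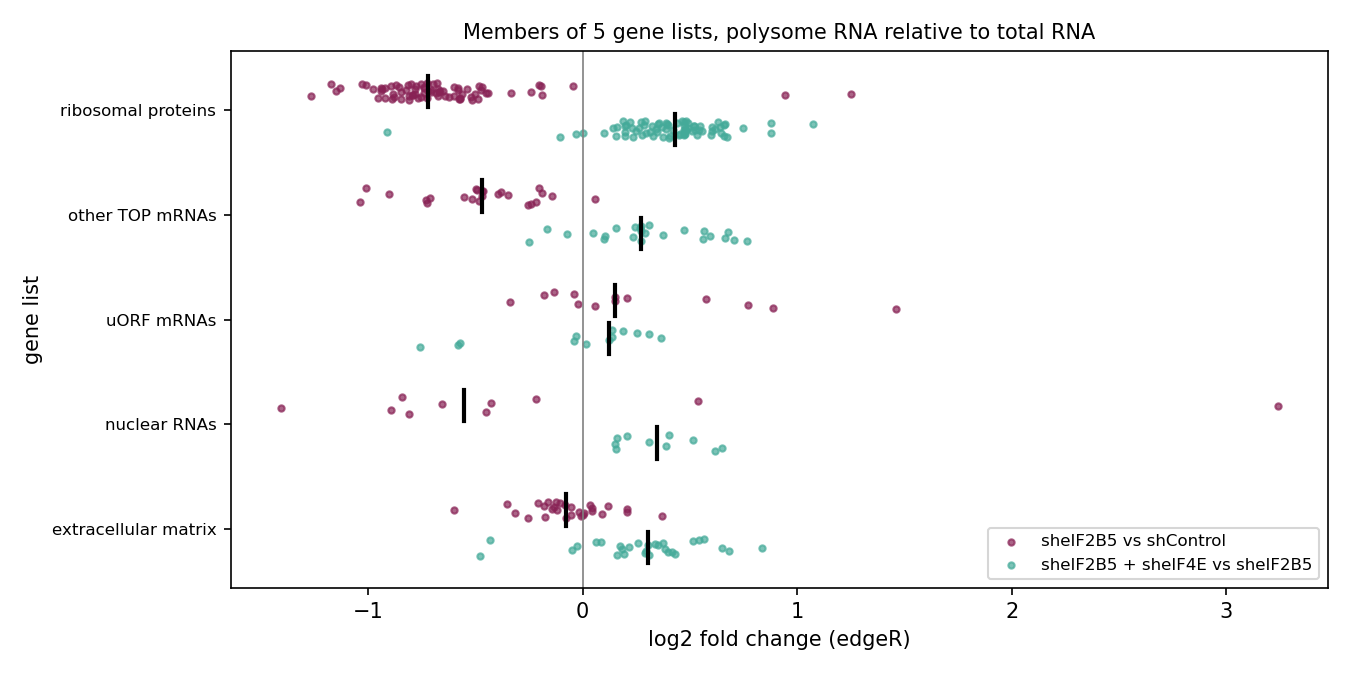
Log2 fold change in polysome RNA beyond that in total RNA (edgeR interaction, horizontal axis) of the members of 5 gene lists, with points for genes and black bars for medians. The median of the 78 ribosomal protein genes lies at -0.72 for sheIF2B5 against shControl and at 0.43 for the combined knockdown against sheIF2B5, on the same side of 0 under each other scaling and filter tried.

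Many genes that moved with sheIF2B5 moved the other way when the Eif4e hairpin was added. In total RNA 3437 genes were higher and then lower and 2264 lower and then higher, against 1699 that moved the same way, so that 77% of genes called in both comparisons went in opposite directions. In Poly 5641 genes (74.3%) and in polysome relative to total RNA 327 genes (81.5%) did. Both comparisons contain the sheIF2B5 libraries, and independent lists of these sizes would give 2201.4 and 1287.7 such genes in Total (50.8% opposite), 1760 and 1765.5 in Poly (50%) and 9.5029 and 102.38 in polysome relative to total RNA (64.2%). Across genes, which are not independent replicates, the covariance of log2 fold changes was -0.39 in Total and -0.44 in Poly, beside -0.02 in the simulations for each. It was -0.06 beside -0.04 for polysome relative to total. The correlation did not part data from simulations: r was -0.443 in Total and in Poly, beside simulated means of -0.496 and -0.476. For polysome relative to total r was -0.372 beside -0.486. Simulated libraries were drawn independently, without deviations shared by a replicate number. When different sheIF2B5 libraries entered each comparison, the share going in opposite directions was 75.8% to 78.1% in Total, 75.9% to 76.8% in Poly and 55.2% to 76.4% in polysome relative to total RNA. Independent lists of the sizes in these divisions would give 50% to 50.2% in Total, 50% in Poly and 48.3% to 65.2% for the last. For the last, correlations of log2 fold changes across genes lay between -0.04 and 0.00441. The count of 327 was 1432 with a replicate block within each fraction, 175 with DESeq2 size factors and 163 without replicate 1 of sheIF2B5 Poly.

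Against shControl, the combined knockdown had higher interferon genes, while ATF4 targets differed in both directions. Interferon genes were higher in 24 and lower in 0 of 25 (median 3.33, adjusted p = 3.07e-35), with Rsad2 at 7.08 ± 0.12 and Ifit3 at 3.81 ± 0.14 in Total. ATF4 targets were higher in 18 and lower in 12 of 41 in Total (median 0.06; 19 and 12 adjusted over the list alone; adjusted p = 0.683) and higher in 21 and lower in 12 in Poly (median 0.19, adjusted p = 0.598). Extl1 (1.84 ± 0.24) and Vldlr (2.13 ± 0.07) stayed higher and Tagln (-1.70 ± 0.06) and Xist (-1.84 ± 0.10) lower. Atf4 was at -0.77 ± 0.04 in Total and at 0.70 ± 0.05 in polysome relative to total RNA, where the block by regression of Poly on Total ended the call (0.312, adjusted p = 0.583). In Poly, Atf4 was at -0.07 ± 0.04 and did not pass (edgeR adjusted p = 0.085), but did with DESeq2 size factors (0.0389) and without replicate 2 of shControl Poly (0.0394) or replicate 4 of the combined knockdown's Poly (0.0281). Eif2b5 was at -3.19 ± 0.07 and Eif4e at -3.65 ± 0.09 in Total, and at -3.58 ± 0.08 and -4.76 ± 0.09 in Poly. Cholesterol synthesis genes were lower in 21 and higher in 0 of 23 (median -0.89, adjusted p = 3.95e-09), with Insig1 at -0.85 ± 0.04. G2/M genes were lower in 23 and higher in 1 of 25 (1.4e-11), with Ccna2 at -0.92 ± 0.05. NRF2 targets were lower in 14 and higher in 3 of 18 (1.4e-08), heat shock genes lower in 13 and higher in 0 of 15 (0.00255), and NF-kB targets higher in 12 and lower in 1 of 14 (2e-05; 13 and 1 adjusted over the list alone). S phase genes were lower in 21 and higher in 3 of 26, with Rrm2 at -0.35 ± 0.04 (0.00204, and adjusted p = 0.243 with an estimated correlation). Map1lc3b stood at -0.40 ± 0.05 and Plau at 2.04 ± 0.06. Ribosomal protein genes were lower in 66 and higher in 0 of 78, or 67 and 0 adjusted over the list alone (1.73e-06, and adjusted p = 0.109 with an estimated correlation). Oxidative phosphorylation genes were lower in 51 and higher in 4 of 74 (2.16e-04, and adjusted p = 0.32 with an estimated correlation), as were mitochondrial ribosome genes in 51 and 10 of 76 (0.00103, and adjusted p = 0.281 with an estimated correlation). The eIF2B subunits were lower in 3 and higher in 1 of 5 (0.0385, 0.0501 with a replicate block within each fraction, up to 0.341 over the alternatives, and adjusted p = 0.0979 with an estimated correlation). Histones were lower in 14 and higher in 0 of 18, or 15 and 0 adjusted over the list alone, without a call (0.162), but had one with that block (0.0151) and without replicate 1 of shControl Total (0.044). In all, 9968 genes changed in Total, 4682 higher and 5286 lower. For lists without a second count, that adjusted over the list alone was the same.

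In Poly, 10176 genes differed between the combined knockdown and shControl, 5060 higher and 5116 lower. Ribosomal protein genes were lower in 71 and higher in 0 of 78 (median -0.90, adjusted p = 2.31e-12), with Rps7 at -1.44 ± 0.04. Other TOP mRNAs were lower in 15 and higher in 3 of 24 (0.0243, 0.0746 with at least 1 CPM in 4 libraries, and adjusted p = 0.501 with an estimated correlation). Interferon genes were higher in 24 and lower in 0 (4.04e-32), NF-kB targets in 11 and 1 (2.07e-05). Lower and higher genes numbered 22 and 0 for cholesterol synthesis (1.04e-08), 22 and 3 for G2/M (1.29e-08), 13 and 3 for NRF2 targets (2.51e-07), 12 and 0 for heat shock (0.00418) and 3 and 1 for eIF2B subunits (0.0122, but 0.0824 with no filter and 0.191 with limma-voom). They numbered 50 and 8 for oxidative phosphorylation (3.1e-04, and adjusted p = 0.351 with an estimated correlation) and 61 and 7 for the mitochondrial ribosome (4.47e-06, and adjusted p = 0.0797 with an estimated correlation). Extl1 was at 1.58 ± 0.19, Vldlr at 2.51 ± 0.07, Rsad2 at 6.75 ± 0.12, Tagln at -1.96 ± 0.06 and Xist at -2.29 ± 0.10. ATF4-type tRNA synthetases were higher in 9 and lower in 2 of 12 (adjusted p = 0.0951, or 0.0433 with a replicate block within each fraction), and histones lower in 13 and higher in 0 of 18 (adjusted p = 0.115, or 0.00919 with that block). Adjusted over the list alone, these counts were the same.

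Relative to total RNA, 3131 genes changed, 1860 higher and 1271 lower, and 5703 did with a replicate block within each fraction. The share of higher genes was 59.4% of calls but 47.3% with DESeq2 size factors. Dync1h1 was at 1.58 ± 0.07, Rps7 at -0.95 ± 0.05, Eif4e at -1.11 ± 0.11 and Eif2b5 at -0.39 ± 0.10, whereas Rpl10 (-0.14 ± 0.08, adjusted p = 0.225) and Atf5 (0.31 ± 0.19, adjusted p = 0.272) did not pass. With the block within each fraction Rpl10 and Atf5 passed (adjusted p = 0.00453 and 0.0407). Ribosomal protein genes were lower in 32 and higher in 0 of 78, or 36 and 0 adjusted over the list alone (adjusted p = 8.91e-12), and uORF mRNAs higher in 4 and lower in 0 of 13 (adjusted p = 0.00434), both held with an estimated correlation. ATF4-type tRNA synthetases were higher in 7 and lower in 0 of 12, or 10 and 0 adjusted over the list alone (2.77e-06, and adjusted p = 0.0564 with an estimated correlation). Other TOP mRNAs were lower in 10 and higher in 2 of 24, or 11 and 2 adjusted over the list alone (0.00371, and adjusted p = 0.397 with an estimated correlation). Mitochondrial ribosome genes were lower in 22 and higher in 8 of 76 (1.5e-04, and adjusted p = 0.27 with an estimated correlation), and matrix genes higher in 14 and lower in 3 of 29, or 15 and 3 adjusted over the list alone (0.00434, and adjusted p = 0.397 with an estimated correlation). Genes listed as sensitive to eIF4E were lower in 6 and higher in 1 of 22 (adjusted p = 0.0251, 0.0839 without number 1 in all groups, and adjusted p = 0.0564 with an estimated correlation). S phase genes were higher in 12 and lower in 4 of 26, or 13 and 4 adjusted over the list alone (adjusted p = 0.0845, or 0.0118 with the block). That list was called without replicate 4 of shControl Poly (0.0222) and without replicate 1 of the combined knockdown's Total (0.038).

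Within shControl, the Poly and Total libraries differed as fractions. Nuclear RNAs were lower in Poly in 10 of 10 (median -2.45, adjusted p = 1.04e-05), and Atf4 was at -1.75 ± 0.04, Eif2b5 at 0.65 ± 0.07 and Eif4e at -0.06 ± 0.08, the last without passing (edgeR adjusted p = 0.516, or 3.19e-05 with a replicate block within each fraction). Of 78 ribosomal protein genes 53 were lower and 13 higher (adjusted p = 1.12e-07, and adjusted p = 0.0734 with an estimated correlation), and all 19 citrate cycle genes were higher (1.12e-07, and adjusted p = 0.0734 with an estimated correlation). In all, 10049 genes differed between the fractions, 5415 higher and 4634 lower in Poly. Adjusted over the list alone, the counts of these lists were the same.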

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

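All tests of explanations in this part, and the division of the sheIF2B5 libraries into numbers 1 and 4 against 2 and 3, were chosen after the results had been seen. The fits without number 1 or number 4 in all groups and those with a replicate block within each fraction were also chosen after that.

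Among 30 groups of 4 libraries examined for a library far from the others (library total, Rn45s share, and CPM of Eif2b5, Eif4e and Atf4), 1 had such a library. Eif2b5 was at 20.84 CPM in replicate 2 of the combined knockdown's Poly, against 25.47 to 25.99 CPM in the other libraries of that group. Chance gives such a gap in about 1 of 20 groups.

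Some effects differed between Total and Poly by the edgeR interaction test. For Eif2b5 the log2 fold change in Poly minus that in Total was -1.13 with sheIF2B5, 0.74 for the combined knockdown against sheIF2B5 and -0.39 against shControl. For Eif4e the interaction was -0.84 for the combined knockdown against sheIF2B5 and -1.11 against shControl. For Atf4 it was 1.46 with sheIF2B5, -0.76 for the combined knockdown against sheIF2B5 and 0.70 against shControl. Genes that changed in opposite directions in Total and Poly and passed the interaction test numbered 50 with sheIF2B5, 206 for the combined knockdown against sheIF2B5 and 201 against shControl. The interaction of Eif2b5 in the combined knockdown against shControl no longer passed without number 1 in all groups (adjusted p = 0.0686).

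Genes that moved with sheIF2B5 and back when the Eif4e hairpin was added made up 77% of the genes called in both comparisons in Total. Both comparisons share the sheIF2B5 libraries. When different libraries entered each, the share stayed at 75.8% in Total and 75.9% in Poly or more. This argues against deviations of single shared libraries as the whole cause. The labels do not say whether libraries came from separate cultures. A deviation common to all sheIF2B5 libraries, as from a single culture, would enter every division, so the divisions cannot weigh it. For polysome relative to total RNA the share fell to 55.2% in 1 division, beside 48.3% for independent lists of its sizes. Shared libraries and a real return cannot be told apart there. With a weaker knockdown of Eif2b5 in the combined libraries, a gene that follows the Eif2b5 level in one direction would stop short of shControl. Of 5701 moved-back genes in Total, 2249 were called short of it. On its other side passed 1470 (25.8%, and 24.7% or more under the 3 scalings tried), which argues against weaker knockdown as the whole cause for those 1470 genes. Of the 34 ATF4 targets that moved back, 16 were called short of shControl and 9 passed on its other side. For the genes that did not pass it, weaker knockdown stays open. Eif2b5 was 0.885 higher (log2) than with sheIF2B5 alone, and no library joined the Eif4e hairpin with Eif2b5 as low as in sheIF2B5. Weaker knockdown may thus account for their return beside an effect of eIF4E loss.

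Interferon genes were higher with sheIF2B5 in 24 of 25 cases and stayed so in the combined knockdown, with a median of 3.33 in Total. Leukocytes among the fibroblasts would bring Ptprc, Tyrobp, Fcer1g, Itgam and Aif1. Their highest mean in a knockdown group was 0.0794 CPM (upper counting limit 0.128), against the 1 CPM predicted and a rise of the interferon genes' sum from 195 to 567 CPM in Total, which argues against leukocytes; the bound of 0.1 CPM first set was passed only by Fcer1g in shControl (0.11), where this explanation predicts nothing. The construct or virus of sheIF2B5 may also raise these genes apart from the loss of Eif2b5. Both knockdown genotypes carry it, no other hairpin against Eif2b5 was used, and so the median of 3.33 cannot be told apart from an effect of eIF2B loss.

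Libraries of a replicate number deviated together within a fraction: 38 of 48 best matches among libraries of another genotype had the same number, and the leading component held 71.9% of the variance of within-group deviations over 9075 genes. The Rn45s share stays open as its cause, with a squared correlation of 0.154 and an upper confidence limit of 0.516 over 24 libraries (permutation tests within groups; Pearson r = 0.392, p = 0.0559, adjusted 0.112; Spearman rho = 0.4, p = 0.0759, adjusted 0.152). Without the 2 farthest libraries r was 0.222. The library total had a squared correlation of 0.00927 over all libraries, with an upper limit of 0.278. By the same permutation tests Pearson r was -0.0963 (p = 0.73, adjusted 0.73) and Spearman rho -0.23 (p = 0.371, adjusted 0.371). Without the 2 farthest libraries r was 0.0363. The pattern lies within fractions, where numbers deviated largely in opposite directions, so a value over both cannot settle it. Within Total r was -0.0235 and within Poly -0.544, so the library total stays open in Poly. A shared day of culture, extraction or sequencing is a candidate source that the labels do not record, and no biological explanation was tested.

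Where libraries exchange freely between groups, splits of them argue against a chance division as the source of differences in Total and between fractions. They do not bear on the size of these differences. Free exchange was not shown. Total libraries of number 1 correlated at 0.9 to 0.943 and of number 4 at 0.744 to 0.813. Between shControl and the combined knockdown all same-numbered Total pairs exceeded 0.1 (0.9, 0.223, 0.342 and 0.813). Total and Poly of shControl number 1 correlated at -0.77. With the 2 groups' libraries alone in the fit, 1 of 35 splits, the real one, gave as many genes in every comparison, and the highest other gave 0. In Poly, and so in polysome relative to total RNA, replicate numbers pair the libraries, as in Total between shControl and the combined knockdown. The 8 splits that part all pairs, the real one included, are too few there for a share under 0.05, with the highest other at 0. The same limit holds wherever numbers pair other Total libraries. The remaining splits keep some pairs on the same side. The splits other than the real one mix groups that differ, which widens the spread within each side. The real split gave 9788 genes in Total, 9911 in Poly and 599 in polysome relative to total RNA for sheIF2B5 against shControl. For the combined knockdown against sheIF2B5 it gave 9810, 9998 and 3516 genes, against shControl 9645, 9985 and 2375, and for Poly against Total within shControl 8999.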

How the results depend on the processing

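Choices of scaling, filter, model and library were set before the data were examined, except the replicate block within each fraction, the fits without number 1 or number 4 in all 6 groups, and the division of shared libraries into numbers 1 and 4 against 2 and 3, which were chosen after the data had been seen.

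Of 10046 values of named genes under alternatives, 9955 kept their call or its absence, 65 lost the call, 11 gained one and 15 changed sign. Of 12026 list results, 11722 kept their call or its absence, 109 lost the call, 192 gained one and 3 changed sign. Direction was compared only where the main fit or the alternative gave a call. Turns in the majority of a list's members are not counted here. Of 489 counts of genes that answer a comparison, 465 stayed within 1.5 times. The other 24 all concern polysome relative to total RNA, and their cause was not tested where none is given.

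For sheIF2B5 against shControl, the 750 genes became 404 with no filter, 3040 with a replicate block within each fraction, 269 with a block pairing Poly and Total of a number, 8497 with a block by regression of Poly on Total, 2566 without number 1 and 368 without number 4 in all 6 groups. For the combined knockdown against sheIF2B5, the 3288 genes became 2136 with DESeq2 size factors, 2184 without ribosomal RNA genes, and 5974, 1922 and 8199 with these 3 blocks. Against shControl, 3131 became 5703, 1933 and 8572 with the blocks. The 327 genes with opposite directions became 175 with DESeq2 size factors, 172 without ribosomal RNA genes, 148 with no filter, 1432, 127 and 4575 with the blocks, 608 without number 1 and 151 without number 4. Fewer libraries lower the power of the last, whereas the rise without number 1 was not tested for its cause. The block pairing Poly with Total assumes that a number shifts both the same way, whereas slopes of Poly on Total were negative for 10397 of 14143 genes (73.5%). The regression allows such slopes and subtracts the slope times the Total change. Where the slope is negative it adds a multiple of that change, so its counts and signs concern a different quantity.

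Leaving out 1 library gave 9682 to 10149 genes in Total, 9781 to 10334 in Poly and 416 to 1003 in polysome relative to total RNA for sheIF2B5 against shControl, the lowest without replicate 1 of sheIF2B5 Poly. For the combined knockdown the ranges were 9238 to 9942, 9418 to 10124 and 2433 to 3607 against sheIF2B5, and 9656 to 10163, 9797 to 10413 and 2714 to 3299 against shControl. For Poly against Total in shControl the range was 9676 to 10209. Genes with opposite directions numbered 5393 to 5738, 5388 to 5818 and 163 to 437, the lowest without replicate 1 of sheIF2B5 Poly.

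The regression block, which estimates a different quantity, gave the opposite sign for 15 named genes called in polysome relative to total RNA. For sheIF2B5 these were Sephs2 (-0.40), E2f1 (-0.019), Ddit3 (3.62) and Malat1 (0.25). For the combined knockdown against sheIF2B5 they were Gdpd1 (0.24), Uchl5 (0.21), Rpl10 (-0.79), Eif3f (-0.14), Aars (-1.16), Tars (-0.12), Iars (-0.84), Fn1 (-0.13), Thbs1 (-0.0944), Mrps30 (0.0584) and Mrpl44 (-0.0849). Among list results with a call in either fit, signed -log10 adjusted p changed sign in these cases. It did for histones with sheIF2B5 without number 1 (-1.44). With fry it did for NRF2 targets (1.31) and p53 targets (1.45) of the combined knockdown against sheIF2B5. Fry does not compare with other genes.

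Scaling moved the balance of directions in polysome relative to total RNA. With sheIF2B5 the higher share of 22.4% became 57.5% with DESeq2 size factors, 38.1% with upper quartiles, 43.6% without ribosomal RNA genes, 40.3% with no filter, 70% with at least 1 CPM in 4 libraries, 56.1% with DESeq2, 47.5% with the regression block, 38.5% without replicate 1 of sheIF2B5 Poly and 93.7% without number 1. For the combined knockdown against sheIF2B5, 75.7% became 36.1%, 56%, 32.2%, 40% with at least 1 CPM, 36.9% with DESeq2, 51.8% with regression and 39% without number 1. Against shControl, 59.4% became 47.3% with DESeq2 size factors, 34.7% without ribosomal RNA genes, 29.8% with only the groups compared, 46.9% with DESeq2, 48.4% with regression and 81.4% without number 1. In Total, 55.1% became 40.4% without number 1 for sheIF2B5, and 41.8% became 53% with at least 1 CPM for the combined knockdown against sheIF2B5.

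The median of all genes shifted by over 0.1 in these cases. In Total these were -0.20 without number 1 with sheIF2B5, 0.11 with DESeq2 size factors or DESeq2, 0.16 with at least 1 CPM, 0.10 with only the groups compared and 0.11 without number 1 for the combined knockdown against sheIF2B5, and 0.12 with upper quartiles against shControl. In polysome relative to total they were 0.11 with at least 1 CPM and 0.23 without number 1 with sheIF2B5, -0.13 with DESeq2 size factors, DESeq2 or regression, -0.14 without ribosomal RNA genes, and -0.12 with at least 1 CPM or without number 1 for the combined knockdown against sheIF2B5, and 0.11 without number 1 against shControl. Poly against Total in shControl shifted by -0.10 with only its groups. With other scalings, other filters on low counts, no ribosomal RNA genes or DESeq2, ribosomal protein genes in polysome relative to total were lower in 51 to 58 with sheIF2B5 and higher in 23 to 36 between the knockdowns. They were not counted with the blocks.

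Trp53 had 0 counts in all 24 libraries, at library totals of 41785442 or more. Counting error alone allows up to 3 counts in a library taken singly, and far fewer per library where all 24 hold 0. Genes under the filter were not tested. GC content was not corrected for, since no genome sequence was at hand, and leaving out mitochondrially encoded genes changed nothing, as the table held none.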

Other observations

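The X-linked test in this part was chosen before its result was seen, and the genes given as single values outside it were chosen after theirs were seen.

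Xist fell with sheIF2B5, from 169 ± 22.3 CPM (SD, n = 4) in shControl Total to 23.1 ± 1.39 CPM, and stood at 47.1 ± 2.44 CPM in the combined knockdown. If the loss of Xist had released the inactive X chromosome, X-linked genes could have risen as a set. The median log2 fold change of 431 X-linked genes in Total minus that of 12876 genes of other chromosomes was -0.116, which argues against such a rise. The camera test of the set pointed down without passing. The Y-linked genes Ddx3y, Kdm5d and Eif2s3y had 0 counts over the 24 libraries and Uty had 1.

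Trp53 had 0 counts in all 24 libraries and its target Cdkn1a 9 to 42 counts per library, while Cdkn2a had 922 to 4533. Ifnb1, an interferon gene, had 0 to 12 counts per library. In Total it had 0 to 4 in shControl, 8 to 12 with sheIF2B5 and 0 to 5 in the combined knockdown. In Poly it had 1 to 4, 0 to 6 and 1 to 5.

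Lars2 stood at 770 ± 290 CPM (SD, n = 4) in shControl Total, 1870 ± 511 CPM with sheIF2B5 and 17600 ± 17100 CPM in the combined knockdown, where libraries ran from 3960 to 41300 CPM and the mean without replicate 4 was 9650 ± 7790 CPM (SD, n = 3). In the combined knockdown's Total libraries its counts rose with the Rn45s share, from 1.46% in replicate 1 to 13.8% in replicate 4. They also rose with that share within the Poly libraries of each knockdown, and the cause was not tested.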
